A study of Mus musculus with 15 samples.

How the data were processed

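Bulk RNA sequencing of 15 mouse libraries was analysed from the deposited gene table. Per the labels' protocols, 500 ng of total RNA was depleted of ribosomal RNA and made into directional libraries. Hearts were perfused before the atria and valves were removed. Groups were taken from the labels: MEF, GT_M2, GT_M2TAD, E12.5 ventricle and adult ventricle, with 3 libraries each. The genome build was mm10 (the same assembly as GRCm38) per the submitters' processing notes. The aligner, the counting tool, the gene annotation and the treatment of strand and of reads shared between genes are not given in the sources used here. Members of families with near-identical copies (actins, myosin heavy chains, globins, glycolytic genes with pseudogenes), overlapping genes and antisense pairs are therefore uncertain.

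Per the file headers the table gives, for each library, expression values, normalized values and transformed values. The deposited expression values are whole-number counts per gene and were used for every test. The normalized values are a signal that the authors made by multiplying the counts of each library by 1 factor, and the log2 values deposited beside them are log2(normalized value + 1). Only the factors were used from these, as an alternative scaling. The table had 49585 rows. In 26 of them the gene name had been turned into a date, and these (at most 0.272% of the counts of a library) were left out. Of the 49559 named rows, 22504 had a count in any library, and 47121 names (95.1%) matched the mouse GENCODE annotation that gave the coordinates.

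Depth ran from 6.40 to 13.3 megacounts (M) per library. Ribosomal-like transcripts were not removed. Within groups, the biological coefficient of variation was 5.27% in MEF, 6.75% in GT_M2, 9.80% in GT_M2TAD, 1.85% at E12.5 and 13.6% in adult ventricle. In simulated counts with known changes for GT_M2TAD versus GT_M2 (13709 genes), the test recovered 62% of 1.5-fold, 84% of 2-fold, 98% of 4-fold and 100% of 8-fold changes and called 0.0888% of unchanged genes. Camera called 0 of 20 unchanged lists in that simulation. Its genes were drawn independently, so it cannot show how often camera calls unchanged lists whose genes vary together. In the real data for this comparison the estimated inter-gene correlation ran from -0.042 (endothelial markers) to 0.57 (reprogramming factors).

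Genes were tested with edgeR 4.0.16 in R 4.3.3 (trimmed mean of M-values normalisation, filterByExpr by group, robust quasi-likelihood fit, Benjamini-Hochberg adjusted p under 0.05). The 9 cultured libraries were fitted together (13826 genes), the 6 ventricle libraries together (13355 genes) and all 15 libraries (14585 genes) for levels relative to ventricle. Standard errors of log2 changes were derived from the change and its F statistic. CPM values were scaled over all 15 libraries, so their ratio can differ slightly from the fitted fold. Fitted log2 changes used a prior count of 0.125. The report's lower bounds use 3 counts over the group, and intervals for ratios with 1 to 3 counts are exact binomial at 95%.

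Before the data were examined, 28 gene lists were fixed, covering heart muscle, metabolism, growth, stress and other cell types. Lists were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, beside an estimated correlation and fry. Also fixed then were the designs and the genes to be named. These were Gata4, Mef2c and Tbx5, the 5 highest and 5 lowest log2 changes among called genes with an average log2 CPM of at least 2, separated groups and no predicted-gene name, up to 3 called members per list with the largest change, and a panel of heart, fibroblast and cofactor genes. About 20 to 30 per comparison are printed. Levels against ventricle are 2 to the power of the median log2 difference of a list. Camera's p for the adult-high and E12.5-high sets was adjusted over 7 sets per comparison, a step added while the report was written, and single-library omissions of these sets used the unadjusted p. Profile similarity used log2 CPM with a prior count of 2. Heart-enriched genes were at least 4-fold higher in ventricle than in MEF. For the adult-high and E12.5-high sets alike, adult ventricle was used for this.

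Alternatives were DESeq2 size factors, DESeq2 1.42.0, limma-voom, no filter on low counts, the replicate number as a block, other sets of libraries in the fit, a 2-fold threshold, omission of mitochondrially encoded genes and omission of each library in turn. The authors' factors, the E12.5 libraries summed as 1, thinning to 1 depth, and the single-library omissions for the correlation, overlap, similarity and shared-effect results were added after seeing the data.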

Results

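RNA was sequenced from mouse embryonic fibroblasts (MEF) and from mouse heart ventricle, all of the ICR strain. Fibroblasts were either control cells or had received retroviruses carrying cardiac transcription factors, and the cultures were collected 4 weeks after transduction. The mixture called GT_M2 held Gata4, Tbx5 and the Mef2c form named Mef2cM2. The mixture called GT_M2TAD held Gata4, Tbx5 and the form named Mef2c_TAD. Such cultures are called induced cardiomyocytes, although a bulk library also measures every cell that was not converted. Ventricle, with atria and valves removed, was taken at embryonic day 12.5 (E12.5) and from 8-week-old adults. Each of the 5 groups had 3 libraries. Total counts, in megacounts (M), were 9.61 to 12.4 in MEF, 8.40 to 9.85 in GT_M2, 10.9 to 13.3 in GT_M2TAD, 6.40 to 7.49 in E12.5 ventricle and 7.75 to 8.92 in adult ventricle. Nothing in the sources states that replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. Levels are normalised CPM, counts scaled to a common library total, as mean ± SD with n = 3 libraries. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named. Folds against a group at 0 counts are lower bounds set at 3 counts over the group, and ratios against 1 to 3 counts carry a 95% interval. Bounds and intervals cover counting error only. Gene coordinates are GRCm38.

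The first comparison asked what Gata4, Tbx5 and Mef2cM2 changed in fibroblasts. Contractile genes that were at or near 0 in MEF were high in GT_M2, while Cxcl13, Inmt and Cx3cr1 fell. Myl7, the atrial myosin light chain (chromosome 11, 5896637 to 5898782), rose from 0 to 88.7 ± 48.2 CPM, at least 1060-fold (adjusted p = 0.00369). Actc1, cardiac actin (chromosome 2, 114047282 to 114053548), rose from 0 to 45.3 ± 21.6 CPM, at least 540-fold (adjusted p = 0.00295). Tnnt2, cardiac troponin T (chromosome 1, 135836354 to 135852260), rose from 0.0899 ± 0.0851 to 146 ± 53.1 CPM, a ratio of 1730 (591 to 8390). Myh6, the alpha myosin heavy chain (chromosome 14, 54941921 to 54966927), rose 1460-fold to 227 ± 94.5 CPM (log2 change 10.5 ± 0.66 SE, adjusted p = 4.13e-05).

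Of 13826 genes tested, 2116 were higher and 1927 lower in GT_M2 than in MEF, and 650 and 416 of them by at least 2-fold. Mstn, which encodes the muscle growth inhibitor myostatin (chromosome 1, 53061640 to 53068079), completed the 5 highest genes with 161 ± 15 CPM and a ratio of 1880 (642 to 9110). Among the lowest were Cxcl13, Inmt, Cx3cr1 and Srcin1. Cxcl13, a B-cell chemokine (chromosome 5, 95956951 to 95961068), fell 92.4-fold from 54.2 ± 4.22 to 0.585 ± 0.2 CPM (adjusted p = 1.06e-10). Inmt, a methyltransferase gene (chromosome 6, 55170626 to 55175043), was 64.2-fold lower (adjusted p = 0.000702). Cx3cr1, the fractalkine receptor gene, was 13-fold lower (adjusted p = 7.87e-05), and Srcin1 was 8.88-fold lower (adjusted p = 4.21e-08). Myl7 missed the threshold when the 6 libraries of both groups were fitted alone (adjusted p = 0.0501, range over alternatives 3.72e-21 to 0.0501).

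The introduced genes were measured with their endogenous copies, since counts per gene do not separate them. Gata4 (chromosome 14, 63198922 to 63271692) rose from 0.188 ± 0.165 to 121 ± 19.5 CPM in GT_M2 (adjusted p = 1.08e-05). Tbx5 (chromosome 5, 119832668 to 119885219) rose from 0.517 ± 0.33 to 114 ± 27.8 CPM (adjusted p = 0.000154). Mef2c (chromosome 13, 83504034 to 83667080) was already at 87.7 ± 4.74 CPM in MEF and rose 1.36-fold to 120 ± 17.8 CPM (adjusted p = 0.00199).

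Counts by list cover only members with enough counts in the cultures to pass the filter. Tested were 33 of 40 fixed sarcomere genes, 24 of 27 for calcium handling, 21 of 30 adult-type and 18 of 20 fetal-type genes. For cardiac transcription factors 17 of 22 were tested, and for epicardial and mesothelial genes 12 of 14. A member near 0 in MEF could pass only through a group where it was higher. The share that rose therefore leaves out members that stayed low. By gene list, 29 of the 33 measured sarcomere genes rose, 1 fell and 3 did not pass, with the same counts when adjusted over the list alone. For calcium handling, 17 of 24 rose and 3 fell, also adjusted over the list alone. Ryr2, the cardiac calcium release channel, rose 253-fold to 105 ± 28.4 CPM, and Atp2a2, the sarcoplasmic calcium pump, rose 1.33-fold. Of 21 adult-type cardiomyocyte genes 16 rose and 2 fell, and of 18 fetal-type genes 10 rose and 2 fell (16 and 2, and 11 and 2, adjusted over the list alone). Of 17 cardiac transcription factors 8 rose and 0 fell, and of 12 epicardial and mesothelial genes 9 rose and 0 fell (8 and 10 rose adjusted over the list alone). In that group Msln rose 16.1-fold to 30.2 ± 5.8 CPM. For cell cycle genes, 12 of 32 fell and 1 rose (15 and 1 adjusted over the list alone), and Tpx2, a spindle gene, fell 1.80-fold. Camera with a preset correlation called these 7 lists (adjusted p = 2.41e-16, 7.86e-05, 1.25e-05, 0.00294, 0.00111, 3.62e-05 and 0.00269 in the order given). With an estimated correlation the adjusted p was 0.167 for the first 6 and 0.476 for cell cycle.

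Fatty acid oxidation genes rose in 12 of 31 cases and fell in 0, and Cd36, a fatty acid transporter, rose 12.2-fold (adjusted p = 2.7e-05). Among 55 oxidative phosphorylation and TCA cycle genes 10 rose and 0 fell, or 12 and 8 rose in the respective lists adjusted over the list alone (camera adjusted p = 0.000361 and 0.00318, and 0.167 and 0.548 with an estimated correlation). Fibroblast and extracellular matrix genes went both ways, with 12 of 39 higher and 17 lower, also adjusted over the list alone, and no call for the list (camera adjusted p = 0.113). Fap fell 2.86-fold and Thbs2 1.79-fold in GT_M2. Macrophage and leukocyte genes fell in 7 of 16 cases and rose in 2 (9 and 3 adjusted over the list alone), and the list was called lower (camera adjusted p = 0.0115, and 0.540 with an estimated correlation). That call was lost without GT_M2 replicate 3 (camera adjusted p = 0.113). Senescence and p53 target genes rose in 9 of 15 cases and fell in 1 (11 and 1 adjusted over the list alone), Ccng1 by 1.78-fold. Inflammation and interferon genes rose in 8 of 23 and fell in 2 (10 and 2 adjusted over the list alone), Lcn2 by 5.46-fold. Camera called both lists higher (adjusted p = 0.000443 and 0.00548, and 0.356 and 0.404 with an estimated correlation).

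The same comparison for Gata4, Tbx5 and Mef2c_TAD also raised contractile genes and gave more calls, 2807 higher and 2427 lower of 13826. Under the authors' scaling factors 2548 were higher and 2714 lower, 48.4% higher against 53.6% here, so which direction held more calls depended on the scaling. Tnnt2 rose to 206 ± 16.4 CPM, a ratio to MEF of 2380 (813 to 11500), and Actc1 to 65.8 ± 8.95 CPM, at least 764-fold. Myl7 rose at least 752-fold to 64.8 ± 9.7 CPM (adjusted p = 0.00354). Nppa, the atrial natriuretic peptide gene (chromosome 4, 148000722 to 148002079), reached 61.2 ± 11.1 CPM, a ratio of 2100 (377 to 83100). Myl1, a fast skeletal and embryonic myosin light chain (chromosome 1, 66924295 to 66945404), rose from 0 to 34.4 ± 2.84 CPM, at least 396-fold (adjusted p = 8.61e-12).

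The 5 lowest genes in GT_M2TAD against MEF were Inmt, Cxcl13, Zpld1, Slc4a10 and Car3. Inmt was at 0 counts, at least 247-fold lower, and Cxcl13 was 85.0-fold lower (adjusted p = 0.000208 and 3.09e-11). Zpld1 was 61.7-fold lower, Slc4a10, a bicarbonate transporter gene, was 23.5-fold lower and Car3, a carbonic anhydrase gene, was 18.7-fold lower (adjusted p = 0.000655, 1.63e-05 and 0.000619). Gata4 reached 113 ± 29.6 CPM and Tbx5 72.7 ± 29.7 CPM (adjusted p = 6.29e-06 and 0.000181), while Mef2c, at 97.4 ± 5.71 CPM, was 1.11 times the MEF level and did not pass (adjusted p = 0.200).

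In GT_M2TAD 30 of 33 sarcomere genes rose and 1 fell, and 17 of 24 calcium handling genes rose and 3 fell, with the same counts adjusted over the list alone. Of 55 oxidative phosphorylation and TCA cycle genes 26 rose and 0 fell (27 adjusted over the list alone). Of 20 glycolysis genes 15 rose and 2 fell, also adjusted over the list alone, and Pfkp rose 2.17-fold (adjusted p = 3.56e-08). Of 38 skeletal muscle markers fixed 18 passed the filter, of which 11 rose and 3 fell, also adjusted over the list alone. Cell cycle genes fell in 17 of 32 cases and rose in 1 (23 and 2 adjusted over the list alone), Bub1b by 2.19-fold. Senescence and p53 target genes rose in 12 of 15 cases and fell in 1, also adjusted over the list alone, with Cdkn2a 2.36-fold and Ccng1 2.34-fold higher. Inflammation and interferon genes rose in 15 of 23 cases and fell in 1 (16 and 1 adjusted over the list alone), with Lcn2 9.66-fold higher. Camera called these 8 lists (adjusted p = 5.44e-15, 3.77e-05, 1.04e-05, 6.92e-06, 0.0069, 3.77e-05, 9.75e-06 and 3.77e-05 in the order given). With an estimated correlation none of the 27 lists tested was called, the smallest adjusted p being 0.162, against 20 lists called by fry, which tests whether a list's genes move on balance in a direction.

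Changes against MEF were alike for both mixtures. Among the 13826 genes, 1818 were higher and 1503 lower with both, where independent lists would share 430 and 338, and Pearson's r of the log2 changes across genes was 0.919 (genes are not independent replicates). Both comparisons share the MEF libraries. Simulated unchanged groups against those controls gave a mean r of 0.487 over 20 simulations with 0 shared higher and 1 shared lower calls on average. The covariance was 0.687 observed and 0.0175 simulated, a difference of 0.670. That difference is what remained after the simulated share of the controls was taken off. The 3 MEF libraries cannot be split into sets of 2, so a share of the controls beyond the simulated one was not tested.

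The direct comparison of GT_M2TAD with GT_M2 asked what the change from Mef2cM2 to Mef2c_TAD altered. Nppa, Myl1 and most glycolysis genes were higher with Mef2c_TAD, and 7 of 17 smooth muscle markers and 7 of 18 skeletal muscle markers rose, whereas Myh6, Myh7, Tnnt2 and Tnni3 did not pass the test. Nppa was 21-fold higher, 61.2 ± 11.1 against 2.85 ± 1.08 CPM (log2 change 4.39 ± 0.21 SE, adjusted p = 1.15e-06). Myl1 was 4.96-fold higher, 34.4 ± 2.84 against 6.96 ± 0.281 CPM (log2 change 2.31 ± 0.12 SE, adjusted p = 3.27e-07). Pgk1, phosphoglycerate kinase (chromosome X, 106187100 to 106203699), was 1.56-fold higher, 149 ± 14.3 against 96.5 ± 7.89 CPM (adjusted p = 0.000138).

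Of 13826 genes 606 were higher and 345 lower in GT_M2TAD than in GT_M2, 951 in all, and 79 and 59 of them by at least 2-fold. The total rested partly on single libraries. It was 615 without GT_M2 replicate 1 and 482 without GT_M2 replicate 2, and 464 of the 951 genes were still called in the latter case. Under the authors' scaling factors the split was 486 higher and 456 lower, 51.6% higher against 63.7% here. Beside Nppa and Myl1, the 5 highest genes held Myh11, Ptprb and Serpinb9b. Myh11, the smooth muscle myosin heavy chain (chromosome 16, 14194535 to 14291372), was 4.12-fold higher (adjusted p = 0.00222), Ptprb, an endothelial receptor phosphatase gene, 4.02-fold (adjusted p = 6.12e-06) and Serpinb9b, a protease inhibitor gene, 3.76-fold (adjusted p = 0.0106). The 5 lowest were Slc4a10 (7.30-fold lower, adjusted p = 0.0104), Dmp1 (3.92-fold, 0.0282), Cntn3 (3.78-fold, 0.000628), Pcp4 (3.05-fold, 0.00133) and Otor (2.97-fold, 0.00166).

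Some of these 10 calls were fragile. Serpinb9b missed the threshold without GT_M2 replicate 3 (adjusted p = 0.0573) and with the 6 libraries of both groups alone (0.0501, range over alternatives 1.77e-06 to 0.0573). Dmp1, a bone matrix gene, missed it without GT_M2 replicate 1, 2 or 3 (adjusted p = 0.0721, 0.0567 and 0.0874) and without GT_M2TAD replicate 1 or 2 (0.0594 and 0.0582), with no filter on low counts (0.0716) and with the 6 libraries of both groups alone (0.0599), with a range over alternatives of 1.44e-05 to 0.0874. Slc4a10 (chromosome 2, 62046462 to 62326730) missed it with limma-voom (adjusted p = 0.0533, range over alternatives 6.27e-09 to 0.0533).

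Of the introduced genes none passed alone between the mixtures, with 1 of the 3 lower when adjusted over the list alone. As a list they were called lower in GT_M2TAD (camera adjusted p = 0.0409, and 0.397 with an estimated correlation), a call lost without GT_M2 replicate 3 (camera adjusted p = 0.143) and without GT_M2TAD replicate 1 (0.0879) or 3 (0.140), with a range over alternatives of 0.00217 to 0.143. Gata4 was at 113 ± 29.6 and 121 ± 19.5 CPM (log2 difference -0.09 ± 0.21 SE, adjusted p = 0.862). Tbx5 was at 72.7 ± 29.7 and 114 ± 27.8 CPM (log2 difference -0.66 ± 0.31 SE, adjusted p = 0.297), and it was called lower without GT_M2TAD replicate 2 (adjusted p = 0.0369, range over alternatives 0.0369 to 0.560). Mef2c was at 97.4 ± 5.71 and 120 ± 17.8 CPM (log2 difference -0.29 ± 0.09 SE, adjusted p = 0.0673), and 3 of its 16 alternatives called it lower (range 0.019 to 0.195). Ep300, which encodes the acetyltransferase p300 named in the series title, was at 189 ± 11.5 and 207 ± 3.3 CPM (log2 difference -0.12 ± 0.06 SE, adjusted p = 0.220).

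Sarcomere genes rose in 9 of 33 cases and fell in 0, or 12 and 2 adjusted over the list alone (camera adjusted p = 1.3e-05, and 0.409 with an estimated correlation). Acta1, skeletal actin, was 11-fold higher at 2.08 ± 0.216 CPM, Synpo2l 3.47-fold and Tcap, a Z-disc protein gene, 2.66-fold (adjusted p = 0.000919, 0.000241 and 0.00478). Tnnt2 (206 ± 16.4 against 146 ± 53.1 CPM), Actc1 (65.8 ± 8.95 against 45.3 ± 21.6 CPM) and Actn2 (25.4 ± 1.81 against 18.4 ± 7.71 CPM) did not pass (adjusted p = 0.290, 0.492 and 0.311). GT_M2 replicate 3 decided this. In GT_M2 replicates 1, 2 and 3 Tnnt2 was at 113, 118 and 207 CPM, and without replicate 3 all of these genes were called higher in GT_M2TAD (adjusted p = 2.44e-05, 0.000551 and 0.00241, with ranges over alternatives of 2.44e-05 to 0.532, 0.000551 to 0.735 and 0.00241 to 0.566). Myh6 was at 154 ± 12.5 against 227 ± 94.5 CPM and Myh7, the beta myosin heavy chain, at 7.38 ± 0.642 against 7.3 ± 4.23 CPM, and neither passed (adjusted p = 0.308 and 0.998). Tnni3 was at 6.52 ± 1.22 against 12.4 ± 6.6 CPM and did not pass (adjusted p = 0.124). Other settings called some of these lower in GT_M2TAD. Myh6 was called with DESeq2 (adjusted p = 0.0393, range over alternatives 0.0393 to 0.464), and 3 of 16 alternatives called Tnni3, among them DESeq2 (0.0384) and the fit without GT_M2 replicate 1 (0.019, range over alternatives 0.019 to 0.331).

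**Figure D1:**
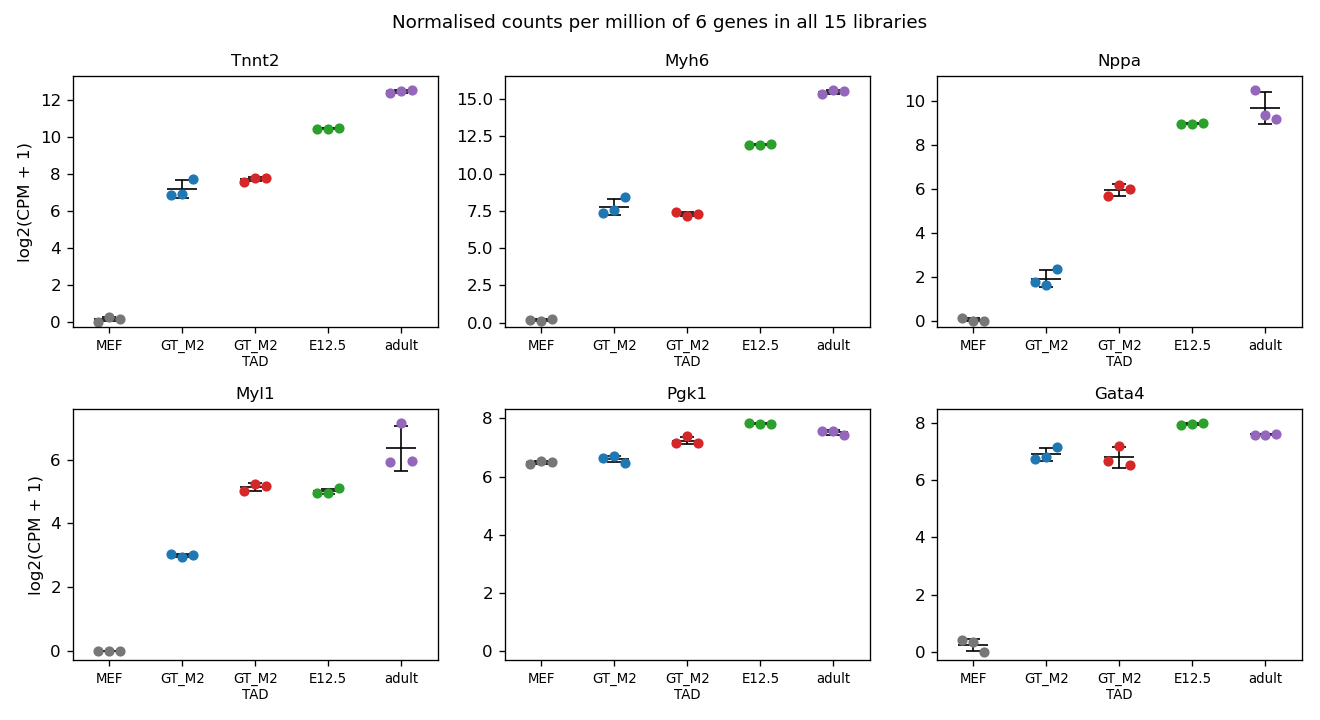
Normalised counts of 6 genes in each library, as log2(CPM + 1) on the y axis, for MEF, GT_M2, GT_M2TAD, E12.5 ventricle and adult ventricle. Points are libraries, horizontal bars means and whiskers SD of the plotted log2 values (n = 3). Nppa and Myl1 separated GT_M2TAD from GT_M2, whereas for Tnnt2 GT_M2 replicate 3 (207 CPM) lay among the GT_M2TAD libraries (187 to 216 CPM).

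Of 18 fetal-type cardiomyocyte genes 4 rose and 1 fell in GT_M2TAD against GT_M2, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.0136, and 0.216 with an estimated correlation). Nppb, the B-type natriuretic peptide gene, was 4.62-fold higher at 3.22 ± 1.13 CPM (adjusted p = 0.0045). In the ventricles here, neither Nppb nor Nppa was called higher at E12.5. Nppb was higher in the adult (log2 change 3.65 with the E12.5 libraries summed as 1), and Nppa did not pass between the stages. Their rise in GT_M2TAD therefore does not mark a shift toward E12.5 ventricle. Hcn4, the pacemaker channel gene, was 4.06-fold lower (adjusted p = 0.0249), a call lost with limma-voom (0.0590), without GT_M2 replicate 2 (0.0518) and without GT_M2TAD replicate 1 (0.0827) or 3 (0.0895), with a range over alternatives of 0.0002 to 0.0895. Of 21 adult-type genes 6 rose and 0 fell, or 6 and 1 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0952). It was called without GT_M2 replicate 3 (camera adjusted p = 0.00656, range over alternatives 0.00643 to 0.388). Hrc and Casq2, which encode calcium-binding proteins of the sarcoplasmic reticulum, were 4.70-fold and 3.05-fold higher (adjusted p = 0.000226 and 0.0102). Fitted with all 15 libraries, Acta1, Synpo2l and Nppb were not called (adjusted p = 0.349, 0.153 and 0.611, the highest of their alternatives, whose lowest were 7.61e-06, 3.56e-11 and 2.94e-05).

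Glycolysis genes were the list with the smallest camera p. In GT_M2TAD 15 of 20 rose against GT_M2 and 0 fell, or 17 and 0 adjusted over the list alone, with a median log2 change of 0.40. Camera's adjusted p was 3.65e-18 with the preset and 0.0395 with an estimated correlation. Besides Pgk1, Slc16a3, a lactate exporter gene, was 1.87-fold higher (adjusted p = 0.00262). In MEF Slc16a3 was at 34.5 ± 6.37 CPM, against 17.5 ± 3.05 in GT_M2 and 32.5 ± 2.33 in GT_M2TAD. Oxidative phosphorylation and TCA cycle genes rose in 3 of 55 cases and fell in 0, also adjusted over the list alone (camera adjusted p = 0.0011, and 0.464 with an estimated correlation), and that list was not called without GT_M2TAD replicate 3 (camera adjusted p = 0.199). Mitochondrially encoded transcripts went the other way, with a median log2 change of -0.14 and 0 of 12 passing, also adjusted over the list alone (camera adjusted p = 0.0336, and 0.464 with an estimated correlation). This call was lost with no filter on low counts (camera adjusted p = 0.0532), without GT_M2 replicate 1 (0.135) or 2 (0.0542) and without GT_M2TAD replicate 1 (0.139), with a range over alternatives of 0.00702 to 0.139. Pdk4, which restrains pyruvate oxidation in mitochondria, was 2-fold higher (adjusted p = 1.72e-06). It belongs to the fatty acid oxidation list, of which 3 of 31 genes rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.114). That list was called without GT_M2 replicate 3 (camera adjusted p = 0.0353, range over alternatives 0.0353 to 0.419).

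Markers of other muscle lineages also differed. Of 17 smooth muscle markers 7 rose and 2 fell in GT_M2TAD, or 12 and 3 adjusted over the list alone (camera adjusted p = 1e-05, and 0.281 with an estimated correlation). Actg2, enteric smooth muscle actin, was 2.49-fold higher (adjusted p = 0.00829). Of the 18 skeletal muscle markers tested (38 were fixed) 7 rose and 2 fell, or 7 and 4 adjusted over the list alone. The list missed camera's threshold (adjusted p = 0.0526), although it passed without GT_M2 replicate 3 (0.0102) and without GT_M2TAD replicate 3 (0.0399), with a range over alternatives of 0.00435 to 0.175. Myh3, the embryonic skeletal myosin, was 18.6-fold higher at 3.55 ± 1.04 CPM and Ryr1, the skeletal calcium release channel, 13.3-fold higher at 4.42 ± 0.544 CPM (adjusted p = 0.000455 and 6.79e-05). Myod1, the skeletal muscle regulator (chromosome 7, 46376474 to 46379099), was at 2.37 ± 0.882 CPM in GT_M2TAD and 0.0776 ± 0.134 CPM in GT_M2, a ratio of 32.2 (8.65 to 270).

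Senescence and p53 target genes rose in 6 of 15 cases and fell in 0 (7 and 0 adjusted over the list alone), with Ccng1 1.32-fold and Cdkn2b 1.30-fold higher. Neuronal and Schwann markers, of which 7 of the 15 fixed were tested, rose in 4 cases and fell in 0 (5 and 0 adjusted over the list alone), Nefm by 3.89-fold. TGF-beta response genes rose in 2 of 18 cases and fell in 0 (4 and 0 adjusted over the list alone), with Inhba 1.52-fold higher. Inflammation and interferon genes rose in 1 of 23 cases and fell in 0 (0 adjusted over the list alone), and cartilage and bone markers fell in 1 of 9 and rose in 0, also adjusted over the list alone. Camera's adjusted p for these lists was 1.52e-06, 0.00102, 0.0136, 0.000848 and 0.00102, and 0.281, 0.281, 0.216, 0.376 and 0.397 with an estimated correlation. Cell cycle genes were called lower as a list (camera adjusted p = 0.0136, and 0.464 with an estimated correlation) with a median log2 change of -0.20 and 0 of 32 members passing, also adjusted over the list alone. The cell cycle call was lost without GT_M2 replicate 1 (camera adjusted p = 0.127) and without GT_M2TAD replicate 2 (0.0722).

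**Figure D2:**
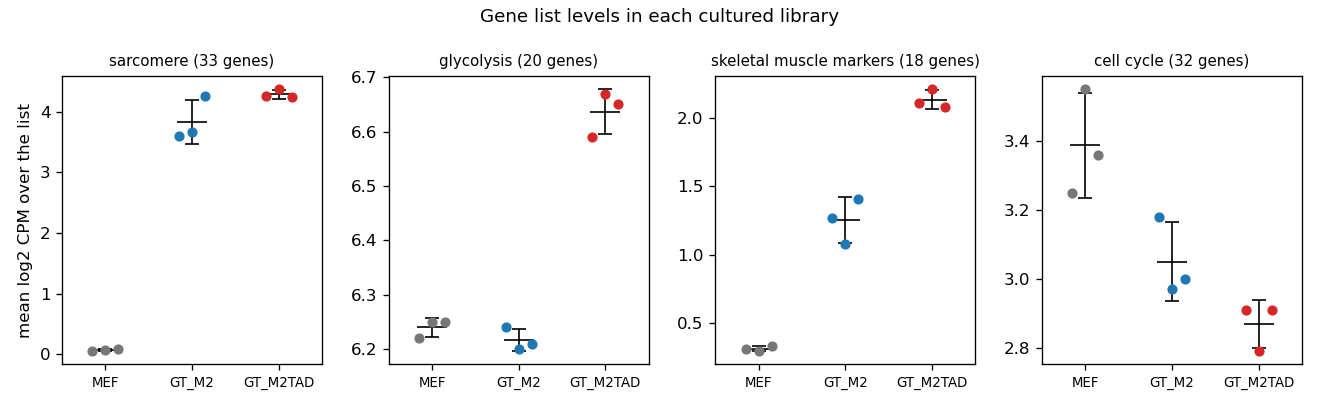
Mean log2 CPM over the tested genes of 4 lists in each cultured library, with a separate y axis range per panel. Points are libraries, horizontal bars group means and whiskers SD (n = 3). The sarcomere mean of GT_M2 replicate 3 (4.25) equalled that of GT_M2TAD replicate 1, and replicates 1 and 2 lay at 3.59 and 3.66.

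The ventricle libraries served as references of immature and mature heart. Adult ventricle had far higher levels of adult contractile, mitochondrial and fatty acid genes than E12.5 ventricle and far lower levels of embryonic globins and cell cycle genes. Myot, a Z-disc protein gene (chromosome 18, 44334074 to 44355724), rose from 0 to 292 ± 43.8 CPM, at least 2520-fold (adjusted p = 5.87e-08). Hbb-y, an embryonic beta-like globin (chromosome 7, 103851749 to 103853216), fell from 3130 ± 25.6 CPM to 0 counts, at least 19300-fold (adjusted p = 5.52e-13). Tnni3, the adult cardiac troponin I, rose 15.5-fold to 3330 ± 260 CPM, while Tnni1, the fetal form, fell 2200-fold from 590 ± 7.33 CPM (adjusted p = 2.85e-12 and 2.26e-11).

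Of 13355 genes tested 5211 were higher and 5340 lower in adult ventricle, and 3046 and 2904 of them by at least 2-fold. Scaling mattered here. With the authors' factors 3360 genes were higher and 7717 lower, 30.3% higher against 49.4% here, and the median log2 change of all genes moved by -0.54, so changes smaller than that depend on the scaling. The other 4 highest genes were Xdh, with a ratio of 5470 (981 to 216000), Xirp2, 2210-fold higher at 1420 ± 440 CPM, Tuba8, with a ratio of 2500 (692 to 20600), and Slc28a2, at least 258-fold higher. Also lowest were Hba-x, at least 3180-fold lower, Hbb-bh1, at least 467-fold lower, Col2a1, at least 650-fold lower, and Igf2bp1, with a ratio of 5830 (1050 to 230000). Gata4 was 1.38-fold and Tbx5 2.33-fold lower in adult ventricle (adjusted p = 1.5e-05 and 2.44e-07), and the Gata4 change was not called in a fit of all 15 libraries (adjusted p = 0.0578, range over alternatives 5.29e-09 to 0.0578). Mef2c was 1.16-fold higher (log2 change 0.21, adjusted p = 0.0178) but turned to -0.33 under the authors' factors, and was not called without E12.5 replicate 2 (0.111), with a range over alternatives of 0.000409 to 0.291.

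All 30 adult-type cardiomyocyte genes rose, and 34 of 40 sarcomere genes rose and 3 fell. Ckmt2, the mitochondrial creatine kinase of striated muscle, rose 919-fold to 2270 ± 221 CPM and Myh6 11-fold to 45700 ± 4670 CPM. Of 58 oxidative phosphorylation and TCA cycle genes 56 rose and 2 fell, of 32 fatty acid oxidation genes 31 rose and 0 fell, and all 13 mitochondrially encoded transcripts rose. Mitochondrially encoded transcripts made up 7.50 to 9.49% of counts in adult ventricle and 1.57 to 1.60% at E12.5. All 32 cell cycle genes fell, Ccnb1 by 146-fold, as did 16 of 20 fetal-type genes, with 2 higher, and 11 of 12 erythroid genes, with 0 higher. Each of these counts was the same adjusted over the list alone. Camera called these 8 lists (adjusted p = 5.15e-14, 1.54e-09, 1.84e-20, 2.29e-12, 9.91e-07, 2.5e-11, 4.19e-05 and 4.84e-05 in the order given), and their adjusted p with an estimated correlation was 0.0911, 0.0911, 0.0911, 0.245, 0.245, 0.164, 0.173 and 0.173.

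Macrophage and leukocyte markers rose in 15 of 16 cases and fell in 1, also adjusted over the list alone, and Cd74 rose 153-fold. Endothelial markers rose in 13 of 16 cases and fell in 3, and epicardial and mesothelial markers fell in 13 of 14 and rose in 0, also adjusted over the list alone, with Bnc1 26.4-fold lower. Camera's adjusted p was 0.000278, 0.00696 and 0.000423, and 0.173, 0.164 and 0.245 with an estimated correlation. Relative to total counts, without further scaling, adult libraries held 0 to 0.112 CPM of 4 Y-linked genes, against 124 to 137 CPM at E12.5, where Xist was at 82.8 to 90.9 CPM, so the sexes were not matched between the groups. The 3 E12.5 libraries differed from each other by little more than counting noise (chi-square per degree of freedom 1.23 to 1.34, against 2.75 to 16.6 within the other groups). They were kept as 3 replicates, and 9025 genes were called when they were summed as 1, a fit in which the spread came from adult ventricle alone and was assumed for E12.5. Nppa did not pass between the stages (889 ± 484 against 498 ± 9.46 CPM, adjusted p = 0.166), and it was called higher without adult replicate 1 (adjusted p = 0.00184) and in a fit of all 15 libraries (0.0211, range over alternatives 0.00184 to 0.694).

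The series title concerns maturation, so the change from Mef2cM2 to Mef2c_TAD was compared with the change from E12.5 to adult ventricle. Genes at least 2-fold higher in adult ventricle shifted slightly upward in GT_M2TAD. Of the 2709 tested 177 (6.53%) rose and 59 (2.18%) fell against GT_M2, with a median log2 change of 0.05. Of the 2640 genes at least 2-fold higher at E12.5, 131 (4.96%) rose and 120 (4.55%) fell, with a median log2 change of -0.05. Over all 13826 genes 606 rose and 345 fell, so more rises than falls was the general pattern. Against all genes, the adult-high set held a larger share of rises and a slightly smaller share of falls. The E12.5-high set held larger shares of both, mainly of falls. Adjusted over the 7 sets tested, limma's camera called both with the preset (adjusted p = 0.0247 for each) and neither with an estimated correlation (adjusted p = 0.144 and 0.102). The adult-high set did not pass without GT_M2 replicate 1, where its median was 0.04, or for its 200 largest changes (adjusted p = 0.146). The E12.5-high set did not pass for its 46 tested heart-enriched genes (adjusted p = 0.970). Heart-enriched here meant at least 4-fold higher in adult ventricle than in MEF, which only 98 of the 2904 E12.5-high genes met. Heart genes low in the adult were thus left out of that result.

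Of the 12620 genes tested in both comparisons, 260 were higher in GT_M2TAD than in GT_M2 and higher in adult than in E12.5 ventricle, where 213 would be shared by chance (odds ratio 1.44, Fisher's exact p = 3.82e-05). Another 164 were lower in both, against 122 by chance (odds ratio 1.76, Fisher's exact p = 1.1e-06). For changes of at least 2-fold in both comparisons the odds ratios were 3.69 (27 shared, 11.6 by chance, Fisher's exact p = 5.39e-06) and 2.53 (12 shared, 6.28 by chance, Fisher's exact p = 0.0212). The log2 changes correlated weakly across genes (Pearson's r = 0.12, Spearman's rho = 0.16), and genes are not independent replicates. The r was 0.087 without GT_M2 replicate 1. Over whole profiles, Spearman's rho to adult ventricle was 0.700 ± 0.001 in MEF, 0.727 ± 0.0054 in GT_M2 and 0.731 ± 0.0028 in GT_M2TAD, and the exact permutation test of GT_M2TAD against GT_M2, which cannot go below 0.1 with 3 libraries against 3, decided nothing (exact two-sided permutation p = 0.400). To E12.5 ventricle it was 0.770 ± 0.0032, 0.780 ± 0.005 and 0.776 ± 0.0023 (exact two-sided permutation p = 0.300).

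Sarcomere and adult-type genes stayed far below both ventricle stages in the cultures, whereas fetal-type genes did not stay below the adult level. The median of 20 fetal-type genes was 9.08% and 10.6% of the E12.5 level in GT_M2 and GT_M2TAD but 172% and 266% of the adult level, with 9 called higher and 8 lower than adult ventricle in GT_M2 and 11 higher and 9 lower in GT_M2TAD. Control MEF already expressed part of this list. Over 18 of its genes the mean log2 CPM was 2.79 in MEF, 4.51 in GT_M2 and 5.07 in GT_M2TAD. List levels of MEF were not set against ventricle, so these shares include a fibroblast baseline of unknown size. The median of 40 sarcomere genes was 3.98% of the E12.5 level in GT_M2 and 4.94% in GT_M2TAD, and 0.502% and 0.658% of the adult level. The median of 30 adult-type genes was 5.84% and 5.87% of the E12.5 level and 0.385% and 0.491% of the adult level, and all 30 were called lower than in adult ventricle with either mixture. Oxidative phosphorylation and TCA cycle genes stood at 38.0% and 40.2% of the E12.5 level and 7.40% and 7.74% of the adult level. Control MEF were near the same level, with a mean log2 CPM over 55 of these genes of 5.63, against 5.75 in GT_M2 and 5.83 in GT_M2TAD. Pln, the inhibitor of the calcium pump, was at 0.0702 ± 0.0613 CPM in GT_M2 and 0.0831 ± 0.0876 CPM in GT_M2TAD, against 63.2 ± 2.06 at E12.5 and 963 ± 94.6 in the adult. Myl2 and Ckmt2 likewise had 0 to 2 counts over each culture group of 3 factor-treated libraries. Fibroblast and extracellular matrix genes had a median of 785% and 834% of the adult ventricle level in GT_M2 and GT_M2TAD.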

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

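The difference between the mixtures was tested directly for each gene below, by the contrast of GT_M2TAD with GT_M2 planned for all genes, and the search for opposite calls was made after the single comparisons. Genes called in opposite directions in the same fit are nearly certain to pass this contrast. Its adjusted p-values are therefore no independent support, and the size of each difference is given by its log2 value. No explanation was tested for these genes.

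Against MEF, 9 genes were called in opposite directions with the GT_M2 and GT_M2TAD mixtures, 5 higher with GT_M2 and lower with GT_M2TAD and 4 the other way. Among the 5, the log2 difference of GT_M2TAD from GT_M2 was -0.801 for Rassf2, -0.749 for Smoc2, -0.694 for Rhbdl3, -0.608 for Cttnbp2 and -0.591 for Podn (adjusted p = 0.000836, 0.00123, 0.00315, 0.000748 and 0.000109). Among the 4 it was 0.716 for Tagln, 0.777 for Loxl2, 0.905 for Loxl4 and 1 for Aldh1l1 (adjusted p = 0.000198, 7.51e-06, 0.000205 and 0.00045). Loxl2 and Loxl4 encode lysyl oxidases, which cross-link collagen, and Tagln encodes the smooth muscle protein transgelin. Loxl2 was at 266 ± 22.8 CPM in MEF, 231 ± 16.8 in GT_M2 and 393 ± 16.4 in GT_M2TAD (n = 3 libraries each). In a fit of all 15 libraries the Loxl2 difference was not called (adjusted p = 0.137, with a range over its alternatives of 1.39e-20 to 0.137).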

How the results depend on the processing

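For the 359 results of named genes, 5295 of 5545 alternatives kept direction and side of the threshold, 232 lost the call, 17 gained a call and 1 reversed it. 37 values called in neither fit changed sign and are counted as kept. For gene lists, 1042 of 1086 alternatives that kept camera's preset did so, with 13 losses and 31 gains. The cause was not tested for any change below unless fewer genes, libraries or a stricter threshold explain it by construction. Alternatives added after seeing the data were the authors' factors, E12.5 summed as 1, thinning, and single-library omissions for the correlations, overlaps and similarities.

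At a 2-fold threshold calls numbered 1066 (GT_M2 versus MEF), 1315 (GT_M2TAD versus MEF), 138 (GT_M2TAD versus GT_M2) and 5950 (adult versus E12.5). With both groups fitted alone, GT_M2TAD versus GT_M2 gave 593 calls, and with single libraries left out 482 to 1002. With DESeq2 it gave 955 and after thinning each cultured library to 8373586 counts 909. Camera with an estimated correlation called 0, 0, 1 and 0 lists in the 4 comparisons and fry 19, 20, 7 and 26, against 15, 13, 13 and 16. In adult versus E12.5 ventricle fry turned the direction of the glycolysis list (adjusted p = 0.000201) and of the smooth muscle list (0.0432), and the authors' factors turned Mef2c to -0.331.

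The adult-high set had a median of 0.0727 for heart-enriched genes (adjusted p = 0.0148, and 0.248 with an estimated correlation), 0.0676 for the 200 largest changes and 0.0371 to 0.0605 with single libraries left out. The E12.5-high set had -0.0378 for genes heart-enriched in the adult and -0.145 for the 200 largest changes (adjusted p = 0.0148, and 0.248 with an estimated correlation). The correlation with adult versus E12.5 was 0.16 as Spearman's rho, 0.17 over called genes and 0.087 to 0.12 with single libraries left out. The correlation of both mixtures' changes was 0.94 over genes called in either, and 0.901 to 0.924 with single libraries left out. The heart split under the authors' factors is given in the report, and a fit of all 15 libraries moved the median of all genes there by 0.12.

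Replicate numbers did not pair the libraries, with correlations of same-numbered deviations from -0.071 to 0.15. With the replicate block calls numbered 4005, 5155, 964 and 10398, and 350 of 359 gene results and 105 of 109 list results kept their call. Small changes can be missed, since 62% of simulated 1.5-fold changes were recovered in GT_M2TAD versus GT_M2.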

Other observations

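The tests of paralogs and of a Myod1 sequence were chosen after the result was seen, and the tests of depth, low oxygen, pooled embryos and other splits were set down before theirs.

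Genes of the response to low oxygen outside glycolysis, a list of 18 written before its test, were also higher in GT_M2TAD than in GT_M2. Of these, 10 rose, 0 fell and 8 did not pass, 17 of 18 log2 changes were positive, and their median was 0.356 (camera p = 1.69e-11 with the preset and 0.00303 with an estimated correlation). Ero1l, an oxidase of the endoplasmic reticulum, rose from 168 ± 1.5 to 273 ± 18.8 CPM (adjusted p = 4.85e-06, n = 3 libraries each). Bnip3, a mitochondrial stress gene, rose from 23.8 ± 1.19 to 36.7 ± 5.31 CPM and Egln3, an oxygen-sensing prolyl hydroxylase gene, from 8.98 ± 2.42 to 15 ± 1.45 CPM (adjusted p = 0.00201 and 0.0104). Vegfa (80.9 ± 4.34 against 69.6 ± 7.36 CPM) and Car9 (3.39 ± 0.291 against 2.68 ± 0.632 CPM) did not pass (adjusted p = 0.122 and 0.450).

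The rise of glycolysis genes in GT_M2TAD was weighed first. The greater depth of the GT_M2TAD libraries was argued against, since 14 glycolysis genes were called higher when every cultured library was thinned to 1 total, against 15 before. A wider response to low oxygen, for example from denser cultures, may contribute, since 10 of 18 such genes outside glycolysis were called higher and 0 lower. The list cannot separate low oxygen from other activators of the same genes, and the Mef2c form itself, which the design varies, stays open as untested.

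Skeletal muscle genes higher in GT_M2TAD were weighed second. Reads of cardiac paralogs counted for skeletal genes were argued against, since each of the 5 called skeletal genes with a listed cardiac paralog exceeded that paralog, with a median difference in log2 change of 3.93 (SE 0.67). Myh3 differed from Myh6 by 4.78 and Ryr1 from Ryr2 by 4.16. The labels do not say what the appended TAD is, and a Myod1 sequence in the construct could raise Myod1 counts, but 6 skeletal genes other than Myod1 also rose, which such reads alone would not give. Whether the Myod1 counts themselves come from a construct stays open, and so does the Mef2c form, as untested.

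The small spread among the E12.5 ventricle libraries was weighed last. Libraries made from 1 pool of embryos of both sexes are a possible explanation. Xist (82.8 to 90.9 CPM of total counts) and 4 Y-linked genes (124 to 137 CPM) were present in each library, and the highest library exceeded the lowest by at most 1.10 times. MEF and GT_M2 libraries, which differed by more than counting noise, also held both, with ratios of 1.07 to 1.26. GT_M2TAD libraries held both with ratios of 1.6 for Xist and 1.2 for the Y-linked genes. The E12.5 value is thus not set clearly apart from MEF and GT_M2, and a pool stays open. With a pool, p-values against E12.5 ventricle would rest on technical spread in that group, and no biological explanation was tested.

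Each comparison of 3 libraries with 3 allows 10 splits, too few for a share under 0.05, the smallest being 0.1. Fitted on the 6 libraries alone, the real split called 4585 genes (GT_M2 versus MEF), 4944 (GT_M2TAD versus MEF), 593 (GT_M2TAD versus GT_M2) and 10551 (adult versus E12.5), and the highest other split 0 in each, so that 1 of 10 splits reached the real value. Every other split puts libraries of both groups on each side, which turns a group difference into spread within sides. The 0 calls therefore cannot decide whether the real split arose by chance. For gene lists the real split called 15, 15, 13 and 16 and the highest other 9, 12, 11 and 18, so that 1, 1, 1 and 4 of the 10 splits called as many. Camera with the preset thus also called lists under mixed labels, although such splits keep part of the group difference.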
